A study of Saccharomyces cerevisiae with 19 samples.

How the data were processed

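Ribosome profiling (13 libraries) and mRNA-seq (6 libraries) of wild-type Saccharomyces cerevisiae BY4741 were analysed. Per the labels' protocols, cells grew to an OD600 of 0.4 in YPD, received cycloheximide for 1 min, were filtered and frozen, and were lysed in a buffer with 100 μg/ml cycloheximide. Extracts for profiling were digested with RNase I, and footprints of 28 to 32 nt from monosome fractions were ligated to a linker, reverse transcribed, circularized and amplified. The protocols do not describe the mRNA-seq extraction separately, the oligonucleotides behind each group name, or the meaning of low. Groups were taken from the sample titles. In some file names the 4N and 4+3N libraries carry 3N and 4N, and a 4+3N library titled as replicate 2 carries replicate 1 among its characteristics; the titles were followed.

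The authors deposited a table of whole-number read counts per gene for each library, with genes without reads left out, which were set to 0 here. Per the submitters' processing notes, CASAVA 1.8 and Bowtie 1.0.0 were used with the sacCer3 genome. The notes used here do not state how reads were assigned to genes, on which strand, or what was done with reads that align to several places. The table of ribosome profiling Nonrandom replicate 1 lists each of 5559 genes a second time with another count; the second list, with a total of 11656814, was used, because it correlated with replicate 2 at a Pearson r of 0.997 across genes (0.959 for the first). Of 5758 gene identifiers, 5754 matched the R64 reference annotation, 5751 of these as protein coding, and 96.5% of gene lengths were multiples of 3. These lengths are called coding lengths below. Since some were not multiples of 3, they may include introns in some genes. No sequences were at hand, so neither GC content nor sequence identity could be computed. Genes with a near-identical copy (238) were marked by name, from A and B gene pairs and known multi-copy families.

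Total counts per library ran from 827353 to 13478946. A floor of 3 counts per library, the limit that a count of 0 allows, came to 0.223 CPM in the library with most reads and 3.63 CPM in the one with fewest. Floors and intervals cover counting error only. Where a group had 0 reads in each library, the fold is a lower bound against the mean floor of its libraries. Such bounds are ratios of CPM and leave out the TMM factors that the tested fold changes carry.

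Genes were filtered with filterByExpr, normalized by TMM and tested by quasi-likelihood F tests in edgeR 4.0.16 (R 4.3.3), two-sided, with Benjamini-Hochberg adjusted p-values and a threshold of 0.05. Standard errors are the absolute log2 fold change over the square root of F. The fits held the 4 standard ribosome profiling groups (residual degrees of freedom 5), the standard and low libraries of Nonrandom and 4+3N (4), the mRNA-seq groups (3), and both assays of Nonrandom, 4N and 4+3N (6). The 17 comparisons were the pairs of preparations in each assay, low against standard within each preparation and the difference of these, the footprint to mRNA ratio in each preparation and its differences. Gene lists (22 with enough tested members) were tested by camera in limma 3.58.1 with a preset correlation of 0.01 and with an estimated one, adjusted within each comparison. The lists, comparisons, tests, the first set of other settings and the rule for named genes were fixed before the data were examined. Of 374 list tests 103 passed with the preset correlation and 12 with an estimated one. Correlations of fold changes that share controls were set beside 20 simulations of unchanged groups, in which libraries were drawn independently, without a replicate block.

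Named genes were up to 8 with the largest rise and up to 8 with the largest fall per comparison, among those that passed with a mean of at least 20 CPM in a compared group and no overlap between the groups' libraries, up to 4 members per list with the smallest p, and fixed marker, mating type and translationally controlled genes. Genes described outside this rule were chosen after their values were seen: EFT1, EFT2, TEF1, TEF2, RPL41A and RPL41B where they did not pass, YEF3 in DualLigation against Nonrandom, and the ORFs TAR1, YLR154C-G, YLR162W and RRT15 on chromosome XII and YPR159C-A on chromosome XVI.

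Whether equal replicate numbers go together was checked on the residuals of each group. Their correlations were 0.574 to 0.776 among standard ribosome profiling groups other than DualLigation (3 of 3 pairs of groups above 0.1). Among the standard and low groups of Nonrandom and 4+3N they were 0.134 to 0.566 (6 of 6). Pairs of a standard with a low group lay between 0.175 and 0.374. In mRNA-seq the correlations were 0.22 to 0.464 (3 of 3). A replicate block was therefore run beside the main tests. Between assays 5 of 9 pairs lay above 0.1, with the lowest at −0.011, and with DualLigation they lay between −0.113 and 0.113, so these were not treated as paired. No comparison had 3 or more samples in both groups, so no regrouping of the samples was run.

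The pipeline was tested on simulated data with known changes. For ribosome profiling 4+3N against Nonrandom it recovered 0%, 25.4% and 72.7% of genes changed by log2 values of 0.5, 1 and 2. Of these 65 calls 0 were false. With the block and without the DualLigation libraries it recovered 82.1%, 98.5% and 100%, with 11 false among 198. For DualLigation against Nonrandom it recovered 3%, 32.8% and 89.4% (4 false among 87), for 4+3N low 16.4%, 74.6% and 95.5% (1 among 125), and for mRNA-seq 40.3%, 92.5% and 97% (4 among 157). For the footprint to mRNA ratio it recovered 52.2%, 92.5% and 98.5%, with 13 false among 175. For the differences of the ratio it recovered 16.4%, 85.1% and 93.9%, with 3 false among 133. The blocked fit also left out DualLigation, so its gain cannot be put to the block alone. Each simulation gave all groups the same spread per gene, whereas the real variation was 32.1% in DualLigation and 5.7% in Nonrandom. Recovery and false calls in fits with DualLigation therefore need not hold for the real libraries.

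Other settings fixed at the outset were DESeq2 1.42.0, RLE normalization, no filter on low counts, thinning to the smallest total, leaving out genes with near-identical copies, the replicate block, fits of the compared groups alone, a minimum of 50 CPM in correlations, and leaving out each library in turn. Settings chosen after seeing the data were a fit without DualLigation, the first list of Nonrandom replicate 1, offsets on coding length with and without the block, a block within each assay, DualLigation replicate 1 alone, fold-change correlations without near-identical copies and without shared controls, and camera with the block. Tables and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.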

Results

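Ribosome-protected fragments and mRNA were sequenced from wild-type budding yeast of the laboratory strain BY4741 (a MATa strain that carries deletions at HIS3, LEU2, MET17 and URA3), in 19 libraries that differ in how they were made. The 13 ribosome profiling libraries fell into 6 groups: DualLigation (n = 3), and Nonrandom, 4N, 4+3N, Nonrandom low and 4+3N low (n = 2 each). The 6 mRNA-seq libraries fell into Nonrandom, 4N and 4+3N (n = 2 each). The series compares linkers and reverse transcription primers with and without random bases (N), to ask how far the preparation biases footprint counts. What low stands for is not stated in the labels. Counted reads in the ribosome profiling libraries came to 6735945, 13478946 and 11586006 in DualLigation, 11656814 and 8798525 in Nonrandom, 10884080 and 10263096 in 4N, and 6906778 and 7678144 in 4+3N. The low libraries held 1622380 and 2667016 (Nonrandom low) and 827353 and 1315044 (4+3N low). The mRNA-seq libraries held 2291853 and 3497303 in Nonrandom, 3304475 and 1838817 in 4N, and 2075213 and 2495472 in 4+3N. The 10 genes with most reads took between 15.63% and 17.47% of reads in every ribosome profiling library other than DualLigation replicates 2 and 3, where they took 25.31% and 24.92%. In those 2 libraries YEF3, which encodes translation elongation factor 3, alone held 9.23% and 9.78% of reads. No label states that replicates are separate cultures, so every p-value measures only the spread between these samples.

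The marker and mating type genes read as follows. LEU2 had 1 read over all 19 libraries, and URA3 and MET17 were listed in none. HIS3, which is deleted only in part in this strain, was listed in every library, with group means from 63.9 to 92.4 CPM (counts scaled to the library total). STE2, the alpha-factor receptor of a cells, lay between 164 and 791 CPM in the group means. STE3, the a-factor receptor of alpha cells, lay between 1.21 and 6.68 CPM, and MF(ALPHA)1, a gene for alpha-factor, was at or under 0.218 CPM in every group. MFA1, a gene for the a-factor precursor, ran from 5.19 CPM in DualLigation to 231 CPM in Nonrandom low.

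Replicates lay close together in every group other than DualLigation. The biological coefficient of variation was 5.7% in Nonrandom, 6.4% in 4N, 7.3% in 4+3N, 7.6% in Nonrandom low and 8.1% in 4+3N low. In mRNA-seq it was 7.6% in Nonrandom, 6.5% in 4N and 5.1% in 4+3N. In DualLigation it was 32.1%, and 30% after every library had been thinned to 827353 reads. Across genes, which are not independent replicates, the Pearson correlation of replicates lay between 0.935 and 0.968 in DualLigation and was 0.996 in Nonrandom. The count list of Nonrandom replicate 1 was chosen for its correlation with replicate 2. The variation and correlation in Nonrandom are therefore no independent measure of its reproducibility.

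**Figure D1:**
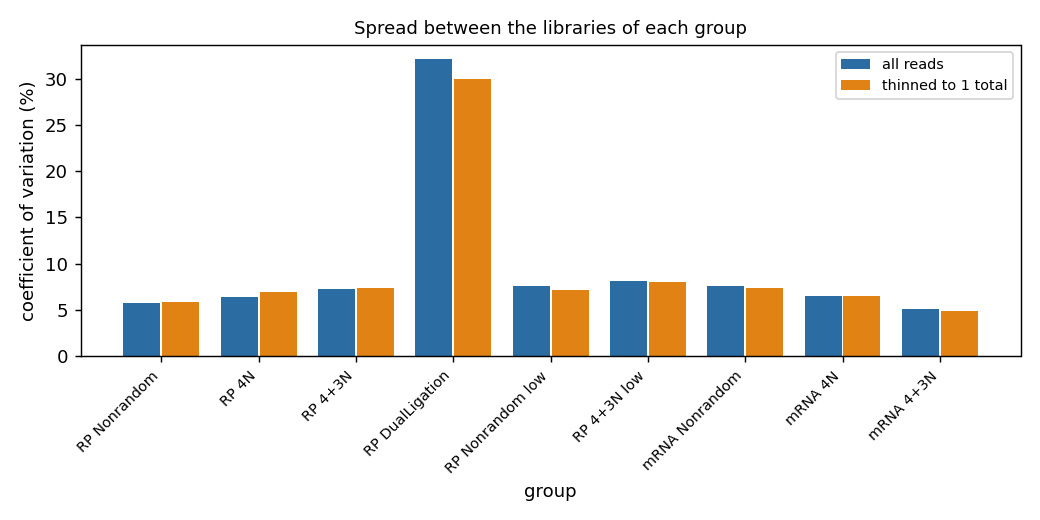
Bars give the biological coefficient of variation between replicates (percent, axis from 0) in each of the 9 groups, from all reads and after thinning every library to 827353 reads. DualLigation stands at 32.1% and 30%, and the other groups at 8.1% or less.

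The comparison of 4N and 4+3N with Nonrandom asked which genes change their footprint counts when random bases are added to the oligonucleotides (n = 2 libraries per group, log2 fold changes throughout). RPL41A, which encodes a very small protein of the large ribosomal subunit, rose in 4+3N by 3.76 (SE 0.32, edgeR adjusted p = 0.00469). TAR1, on chromosome XII from 454696 to 455070 and overlapping the 25S ribosomal RNA gene RDN25-1, had 0 reads in Nonrandom against 110 ± 27.7 CPM (SD) in 4N, at least 368-fold higher, and 129 ± 22.7 CPM in 4+3N, at least 431-fold higher. TAR1 was the gene that passed in 4N, and TAR1 and RPL41A were the 2 that passed in 4+3N.

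TEF1 and TEF2, which encode the same protein, elongation factor 1 alpha, stood at 13 ± 2.05 and 11.1 ± 0.292 CPM in Nonrandom, 37.7 ± 4.45 and 37.9 ± 0.501 CPM in 4N, and 132 ± 17.7 and 114 ± 10.4 CPM in 4+3N (SD, n = 2). Their changes in 4+3N, 3.35 (SE 0.54, adjusted p = 0.142) and 3.38 (SE 0.48, adjusted p = 0.0783), did not pass, nor did RPL41B at 3.31 (SE 0.46, adjusted p = 0.0783). The fit behind these edgeR p-values pooled in the spread of DualLigation, where TEF1 stood at 60.4 ± 49.9 CPM and TEF2 at 140 ± 97.5 CPM (SD, n = 3). It also left out the replicate block. A change that did not pass in this fit is therefore no sign of unchanged counts. EFT1 and EFT2, which encode the same elongation factor 2, had changes of 3.29 (SE 0.74) and 3.28 (SE 0.82) in 4+3N and did not pass. Among the 11 elongation factor genes tested, none passed over all genes, and adjusted over the list alone 4 rose and 0 fell in 4+3N and 1 rose and 0 fell in 4N. The list was higher than other genes by camera in 4+3N (median 0.10, adjusted p = 3.17e-18; adjusted p = 0.00474 with an estimated correlation) and in 4N (median 0.06, adjusted p = 6.53e-09; adjusted p = 0.026 with an estimated correlation), with the largest rises in TEF1, TEF2, EFT1 and EFT2. The 82 large-subunit ribosomal protein genes were higher in 4+3N (1 rose, 0 fell, adjusted over the list alone 3 rose; adjusted p = 1.04e-09; adjusted p = 0.607 with an estimated correlation) and in 4N (none passed, adjusted over the list alone 1 rose; median 0.03, adjusted p = 0.0039; adjusted p = 0.794 with an estimated correlation). The 57 small-subunit genes were higher in 4+3N with none passing (adjusted p = 0.021; adjusted p = 0.607 with an estimated correlation). The 28 cell wall and GPI-anchored protein genes were lower in 4+3N with none passing (median −0.11, adjusted p = 0.00697; adjusted p = 0.607 with an estimated correlation). Between 4+3N and 4N, elongation factors (median 0.04, adjusted p = 1.8e-14; adjusted p = 0.00829 with an estimated correlation), large-subunit genes (adjusted p = 2.59e-09), small-subunit genes (adjusted p = 0.00321) and ribosome biogenesis genes (adjusted p = 0.00609) were higher in 4+3N and cell wall genes lower (median −0.11, adjusted p = 0.000667). Each of the last 4 had an adjusted p = 0.559 with an estimated correlation.

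With replicate numbers as a block, in a fit without DualLigation, far more genes passed. In 4+3N against Nonrandom 17 genes rose over 2-fold, among them TEF2 at 3.37 (SE 0.09, adjusted p = 1.53e-17), TEF1 at 3.34 (SE 0.11, adjusted p = 5.58e-16) and RPL1A, of the large ribosomal subunit, at 1.30 (SE 0.10, adjusted p = 1.09e-08). SED1, a major GPI-anchored cell wall glycoprotein, fell by 0.58 (SE 0.06, adjusted p = 2.24e-07), and AGA1, the anchoring subunit of a-agglutinin, fell by 0.46 (SE 0.06, adjusted p = 6.12e-05). In 4N against Nonrandom, TEF2 rose by 1.78 (SE 0.10, adjusted p = 8.73e-11), TEF1 rose by 1.53 (SE 0.13, adjusted p = 1.02e-07) and SED1 fell by 0.23 (SE 0.05, adjusted p = 0.0326). In 4+3N against 4N, TEF1 rose by 1.81 (SE 0.09, adjusted p = 4.96e-12), SED1 fell by 0.35 (SE 0.06, adjusted p = 0.00114) and CCW12, a cell wall mannoprotein, fell by 0.26 (SE 0.05). In blocked 4+3N against Nonrandom 37 large-subunit genes rose and 6 fell, 17 small-subunit genes rose and 4 fell, 5 elongation factors rose and 0 fell, and 0 cell wall genes rose and 11 fell (adjusted p = 1.9e-08; adjusted p = 0.452 with an estimated correlation). Of the 293 rises in this comparison 67 were of genes with a near-identical copy. No list, here or in the other comparisons, was tested without such genes. List calls for ribosomal proteins and elongation factors therefore cannot be told apart from how reads of copies were counted. Blocked calls also came for glycolysis (5 rose, 0 fell; adjusted p = 0.00605), chaperones (5 rose, 0 fell; adjusted p = 0.00907), ribosome biogenesis (12 rose, 1 fell; adjusted p = 0.0147), the vacuolar ATPase (5 rose, 1 fell; adjusted p = 0.0149), histones (5 rose, 1 fell; adjusted p = 0.0378), the proteasome (6 rose, 0 fell; adjusted p = 0.0423) and genes of a cells (0 rose, 4 fell; adjusted p = 0.0423). With an estimated correlation no list passed under the block, elongation factors included (adjusted p = 0.287), and the others stood at 0.452 or, for the proteasome, 0.542. In blocked 4N against Nonrandom 13 large-subunit, 7 small-subunit and 4 elongation factor genes rose and 0 fell (elongation factors adjusted p = 0.549 with an estimated correlation), with a further call for glycolysis (adjusted p = 0.0479; adjusted p = 0.549 with an estimated correlation). In blocked 4+3N against 4N 9 large-subunit, 6 small-subunit and 4 elongation factor genes rose and 4 cell wall genes fell. Elongation factors had an adjusted p = 0.0816 with an estimated correlation. A further call came for chaperones (adjusted p = 0.0142, and 0.411 with an estimated correlation). With an estimated correlation 0 lists passed in blocked 4N against Nonrandom and 0 in blocked 4+3N against 4N.

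Of 5300 genes tested by edgeR without the block, 1 passed in 4N against Nonrandom (13 at an unadjusted p under 0.05), 2 in 4+3N against Nonrandom (27) and 0 in 4+3N against 4N (7; 1 by DESeq2). With the block these counts were 59 (55 up, 4 down), 490 (293 up, 197 down) and 32 (22 up, 10 down). Without the DualLigation libraries and without the block they were 7, 16 and 6. Genes with a near-identical copy made up 30 of the 59, 76 of the 490 and 18 of the 32. Without such genes and without the block, 0 genes passed in each of the 3 comparisons. For 4N against Nonrandom the count was 3 without DualLigation replicate 1, 2 without Nonrandom replicate 1 or replicate 2, and 0 without 4+3N replicate 1 or replicate 2. For 4+3N against Nonrandom it was 8 without DualLigation replicate 1, 5 without DualLigation replicate 3, and 0 without 4+3N replicate 2. The call of RPL41A was lost without Nonrandom replicate 1 (adjusted p = 0.121) or replicate 2 (adjusted p = 0.0933), without 4+3N replicate 2 (adjusted p = 0.06) and with length offsets (adjusted p = 0.0895). TEF1, TEF2, EFT1, EFT2, RPL41A, RPL41B, TAR1, RPL1A and other genes with near-identical copies have uncertain values, since how reads that align to several places were counted is not stated.

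**Figure D2:**
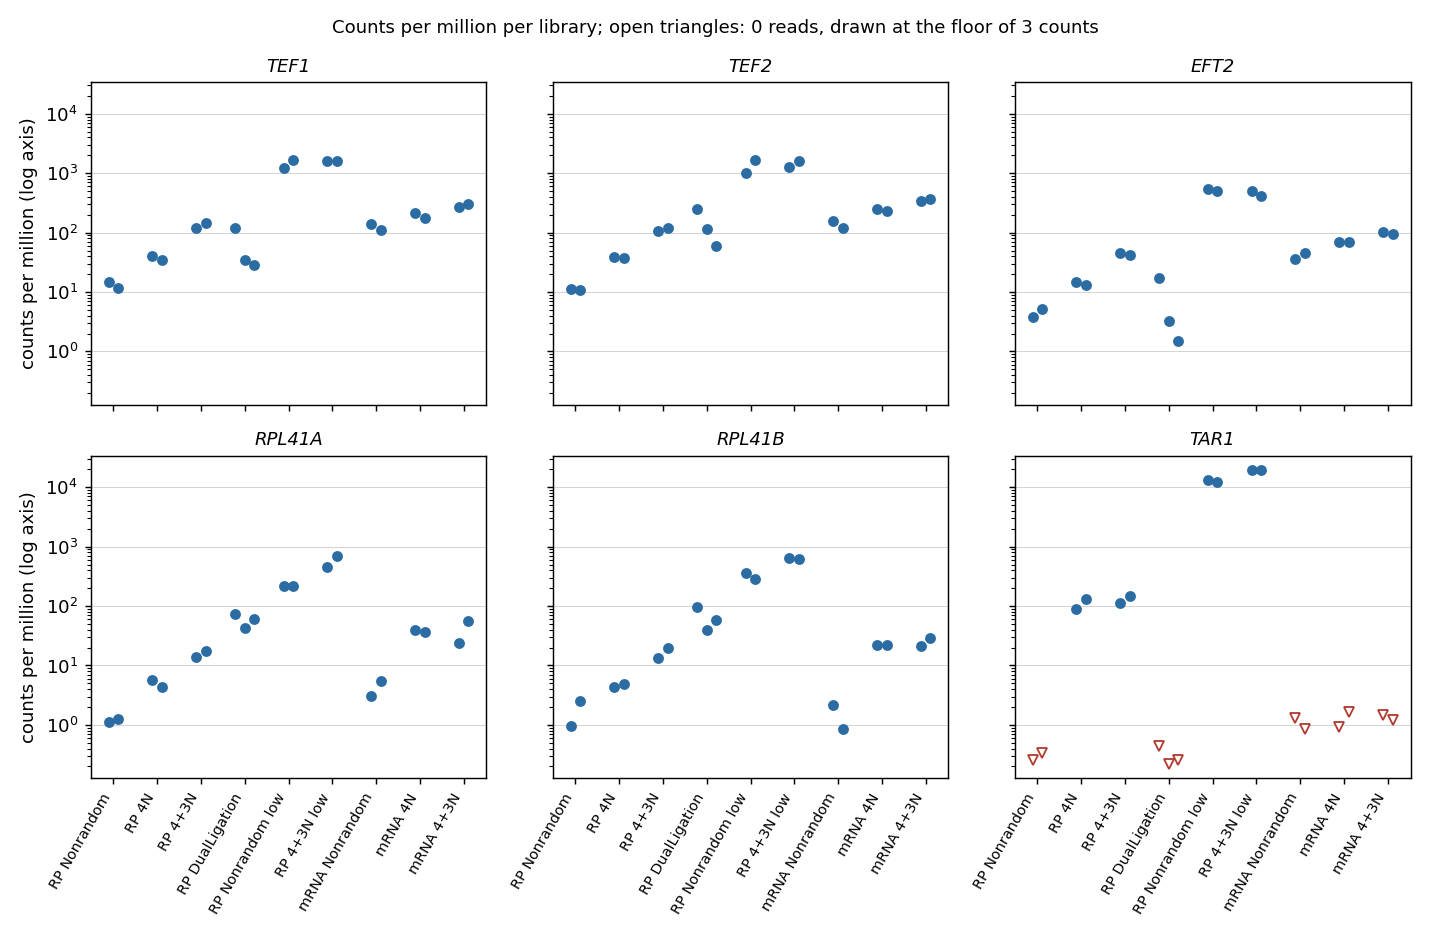
Points give the CPM (log axis) of TEF1, TEF2, EFT2, RPL41A, RPL41B and TAR1 in each library of the 9 groups, with open triangles at the floor of 3 counts where a library had 0 reads. TEF1 runs from a mean of 13 CPM in Nonrandom to 132 CPM in 4+3N and 1440 CPM in Nonrandom low, and TAR1 has 0 reads in Nonrandom, DualLigation and mRNA-seq.

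The low libraries were compared with the standard libraries of the same preparation (n = 2 per group). In Nonrandom low, the same copy pairs were far higher, with RPL41B up by 7.67 (SE 0.22, adjusted p = 1.84e-15), EFT1 by 7.01 (SE 0.23, adjusted p = 8.59e-15), TEF2 by 6.94 (SE 0.19, adjusted p = 6.25e-16) and TEF1 by 6.83 (SE 0.15, adjusted p = 9.28e-18). TEF1 stood at 1440 ± 289 CPM (SD) in Nonrandom low and 1590 ± 8.4 CPM in 4+3N low. In 4+3N low, RPL41B rose by 5.39 (SE 0.17, adjusted p = 1.27e-14), TEF2 by 3.77 (SE 0.16, adjusted p = 8.42e-13) and TEF1 by 3.71 (SE 0.12, adjusted p = 1.41e-14). TAR1 reached 12900 ± 918 CPM in Nonrandom low, at least 43100-fold above its 0 reads in Nonrandom, and rose by 7.34 (SE 0.13) in 4+3N low to 19200 ± 16.6 CPM. TAR1, YLR154C-G, YLR162W, RRT15 and YPR159C-A together held 2.59% and 2.69% of reads in the Nonrandom low libraries and 4.91% and 4.23% in the 4+3N low libraries, against 0.0258% and 0.0321% in 4+3N. The 5 ORFs were grouped after their values were seen. YLR154C-G, on chromosome XII from 462522 to 462671, overlaps the 25S ribosomal RNA gene RDN25-2, while YLR162W and RRT15 on chromosome XII and YPR159C-A on chromosome XVI overlap no annotated ribosomal RNA gene.

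Other genes moved less. In Nonrandom low MFA1 and MFA2, which encode the a-factor precursor, rose by 0.88 (SE 0.11, adjusted p = 9.21e-05) and 0.93 (SE 0.14, adjusted p = 0.000453). RPS30A of the small ribosomal subunit fell by 0.74 (SE 0.16, adjusted p = 0.0136), RPS17B fell by 0.63 (SE 0.09, adjusted p = 0.000326) and RPL37B of the large subunit fell by 0.61 (SE 0.11, adjusted p = 0.00331). In 4+3N low ATF2, an alcohol acetyltransferase, fell by 0.98 (SE 0.21, adjusted p = 0.0302) and ROX1, a repressor of hypoxic genes, fell by 0.74 (SE 0.16, adjusted p = 0.0237). Without one or other low library of its preparation the call was lost for RPS30A (adjusted p = 0.243 and 0.186), ATF2 (adjusted p = 0.152 and 0.347) and ROX1 (adjusted p = 0.131 and 0.32), and for RPL37B without Nonrandom low replicate 2 (adjusted p = 0.165). It was lost too for RPS30A without Nonrandom replicate 1 (adjusted p = 0.25) or either 4+3N low library (adjusted p = 0.0661 and 0.0671), and for ATF2 and ROX1 without 4+3N replicate 1 (adjusted p = 0.0958 and 0.0775), without near-identical copies (adjusted p = 0.0752 and 0.0593) and after thinning (adjusted p = 0.423 and 0.152). ATF2 also lost it without Nonrandom low replicate 2 (adjusted p = 0.0515). Elongation factor genes rose in 4 of 11 cases and fell in 0 in each preparation (adjusted over the list alone 4 rose; adjusted p = 1.94e-66 in Nonrandom, 0.00426 with an estimated correlation, and 1.07e-42 in 4+3N, 0.0128 with an estimated correlation). In Nonrandom the list's median was −0.02 while its mean and test pointed up, and in 4+3N its median was 0.07. Large-subunit genes rose in 13 cases and fell in 13 in Nonrandom low (adjusted over the list alone 16 rose and 24 fell; median −0.01 with mean and test up; adjusted p = 0.0212). That call was lost with an estimated correlation (adjusted p = 0.978) and with the block (adjusted p = 0.17). In 4+3N low 13 large-subunit genes rose and 0 fell (adjusted over the list alone 21 rose and 4 fell; adjusted p = 9.87e-11; adjusted p = 0.959 with an estimated correlation). Small-subunit genes had 0 rises and 8 falls in Nonrandom low (adjusted over the list alone 2 rose and 11 fell; adjusted p = 0.113). In 4+3N low they had 3 rises and 2 falls (adjusted over the list alone 12 rose and 3 fell; adjusted p = 0.0513), and with the block 16 rises and 2 falls (adjusted p = 0.00287; adjusted p = 0.901 with an estimated correlation).

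The change from standard to low libraries itself differed between the preparations for 12 genes, 10 of them with a near-identical copy. RPL42B had the larger change in 4+3N, by 0.64 (SE 0.13, adjusted p = 0.0431), a call that was lost without any single library other than 4+3N replicate 1 (adjusted p from 0.0775 to 0.374), after thinning (adjusted p = 0.0829) and with length offsets (adjusted p = 0.0577). The other 11 had the larger change in Nonrandom, among them EFT1 at −3.78 (SE 0.32), EFT2 at −3.40 (SE 0.21), TEF2 at −3.17 (SE 0.23), TEF1 at −3.12 (SE 0.18, adjusted p = 4.85e-10) and RPL41B at −2.28 (SE 0.34, adjusted p = 0.00156). After thinning RPL41B stood at −0.88 (adjusted p = 0.999), and without 4+3N low replicate 2 its adjusted p was 0.0502. By list, elongation factors had 0 positive and 4 negative differences (median 0.03, mean and test negative; adjusted p = 2.14e-37; adjusted p = 0.0146 with an estimated correlation). Large-subunit genes had 1 positive and 4 negative (median 0.07 and test positive, mean negative; adjusted p = 0.0339), and small-subunit genes had none that passed (median 0.16; adjusted p = 2.04e-08; adjusted p = 0.988 with an estimated correlation for each of these 2 lists).

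Of 5174 genes tested, 75 passed in Nonrandom low (52 up, 23 down) and 38 in 4+3N low (34 up, 4 down), with 24 rises and 1 fall shared. Genes with a near-identical copy made up 44 of the 75 and 25 of the 38. Without such genes the counts were 20 and 10, and 2 for the difference between preparations. With the replicate block they were 198 (130 up, 68 down), 135 (103 up, 32 down) and 51 (35 up, 16 down). The Nonrandom low count was 37 without its low replicate 1 and 36 without its low replicate 2, and the 4+3N low count was 20 and 21 without its low replicates 1 and 2. Leaving out a library gave 8 to 18 genes for the difference between preparations.

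DualLigation libraries (n = 3) differed from Nonrandom (n = 2) across much of the genome. IMD4, an inosine monophosphate dehydrogenase, stood at 38500 ± 8250 CPM (SD) in DualLigation against 445 ± 8.07 CPM in Nonrandom, a rise of 7.17 (SE 0.39, adjusted p = 1.92e-05). CDC21, thymidylate synthase, rose by 6.69 (SE 0.89, adjusted p = 5e-04), AAC1, a mitochondrial ADP/ATP carrier, rose by 6.16 (SE 0.66), BUB2, of the mitotic exit network, by 6.15 (SE 0.80) and RPS22B, of the small ribosomal subunit, by 4.69 (SE 0.16, adjusted p = 5.38e-06). HMF1 fell by 4.92 (SE 0.57, adjusted p = 0.000271), MFA1 fell by 4.17 (SE 0.52, adjusted p = 0.000374), from 131 to 5.19 CPM, OST2, of the oligosaccharyltransferase, fell by 4.09 (SE 0.49) and RPL29, of the large ribosomal subunit, fell by 3.97 (SE 0.46). YEF3 stood at 72000 ± 40100 CPM against 13600 ± 140 CPM. YOL013W-A had 0 reads in Nonrandom and was at least 131-fold higher in DualLigation.

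Most functional groups split, with members going both ways. Mitochondrial ribosomal proteins were lower on balance, with 14 of 70 up and 40 down (adjusted over the list alone 14 up and 43 down), although MRPS8 rose by 4.41 (SE 0.36) where MRPL31 fell by 3.55 (SE 0.41). Enzymes of the tricarboxylic acid cycle were lower, with 1 of 15 up and 10 down (adjusted over the list alone 1 up and 11 down), led by aconitase ACO1, which fell by 1.76 (SE 0.14, adjusted p = 6.66e-05), and citrate synthase CIT1, which fell by 1.40 (SE 0.17). These were the 2 lists that passed by camera (adjusted p = 0.0177 and 0.031), and they did not pass with an estimated correlation (adjusted p = 0.593 and 0.61). Elongation factors rose in 6 of 11 cases and fell in 0. Proteasome genes rose in 16 of 34 cases and fell in 8, with PUP3 up by 2.65 (SE 0.15) and PRE8, which fell by 1.49 (SE 0.12). Amino-acid biosynthesis genes under the activator Gcn4 rose in 20 of 39 cases and fell in 9, among them THR1 at 2.83 (SE 0.21) and ARG8 at 2.57 (SE 0.22). Large-subunit ribosomal proteins rose in 20 of 82 cases and fell in 29 (median −0.21 where the mean was 0.01), and small-subunit ones rose in 21 of 57 and fell in 19. Glycolysis genes rose in 2 of 20 cases and fell in 8, with GPM1, phosphoglycerate mutase, at −1.37 (SE 0.15). Respiratory chain genes rose in 5 of 34 and fell in 15, genes of a cells rose in 1 of 13 and fell in 7, with AGA1 at −3.21 (SE 0.23), and histones rose in 1 of 10 and fell in 6. Ribosome biogenesis genes rose in 19 of 54 and fell in 12, initiation factors rose in 9 of 26 and fell in 5, and aminoacyl-tRNA synthetases rose in 8 of 20 and fell in 6. Chaperones rose in 8 of 24 and fell in 6, the vacuolar ATPase in 5 and 6 of 17 (median −0.34 where the mean was 0.01), methionine and sulfate assimilation in 5 and 3 of 19, and general stress genes in 4 and 6 of 28. Cell wall genes rose in 6 of 28 and fell in 8, genes with upstream ORFs or other translational control rose in 4 of 23 and fell in 4, genes of alpha cells rose in 0 of 3 and fell in 2, and meiosis genes rose in 0 of 11 and fell in 1.

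Of 5300 genes, 2960 passed against Nonrandom (1535 up, 1425 down; 1007 and 830 of them by over 2-fold). Against 4+3N (n = 2), 2893 passed (1510 up, 1383 down), and 1448 rises and 1272 falls were shared with the comparison to Nonrandom. The fit pooled the spread of DualLigation, at 32.1%, with that of groups at 7.3% or less. In fits of the 2 compared groups alone 2092 genes passed against Nonrandom and 2026 against 4+3N. IMD4 rose against 4+3N by 7.21 (SE 0.39, adjusted p = 2.08e-05) and YEF3 by 3.12 (SE 0.62, adjusted p = 0.00344). Mitochondrial ribosomal proteins (13 rose, 42 fell; adjusted p = 0.00656) and the tricarboxylic acid cycle (1 rose, 11 fell; adjusted p = 0.0154) were lower against 4+3N too, each with an adjusted p = 0.704 with an estimated correlation. TAR1 and YLR154C-G had 0 reads in DualLigation, at least 417-fold and at least 259-fold lower than in 4+3N on CPM. These bounds would be lower with the TMM factors of the fit (0.661 to 0.869 in DualLigation, 1.128 and 1.193 in 4+3N). The count against Nonrandom was 1880 without Nonrandom replicate 1 and 1919 without Nonrandom replicate 2, and that against 4+3N was 1840 without 4+3N replicate 1 and 1903 without 4+3N replicate 2.

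In mRNA-seq (n = 2 per group) the same comparison of preparations gave rises, many of them of the same gene pairs, and no falls that passed. Genes with a near-identical copy made up 10 of the 12 that passed in 4+3N and 7 of the 10 in 4N. RPL41B rose by 4.13 (SE 0.37, adjusted p = 2.04e-05) in 4+3N and 3.96 (SE 0.38, adjusted p = 8.99e-05) in 4N, and RPL41A rose by 3.15 (SE 0.39, adjusted p = 0.000362) and 3.08 (SE 0.39, adjusted p = 0.00129). TEF2 rose by 1.34 (SE 0.11, adjusted p = 7.73e-06) in 4+3N and 0.83 (SE 0.11, adjusted p = 0.00159) in 4N, and EFT1 rose by 1.40 (SE 0.18, adjusted p = 0.000395) in 4+3N. RPL35A, of the large ribosomal subunit, rose by 1.22 (SE 0.16) in 4+3N and 0.90 (SE 0.16, adjusted p = 0.037) in 4N. TEF1 stood at 126 ± 19.9 CPM (SD) in Nonrandom, 194 ± 25.8 CPM in 4N and 285 ± 24.8 CPM in 4+3N. Large-subunit genes rose in 6 of 82 cases in 4+3N and 4 in 4N and fell in 0 (adjusted over the list alone 9 and 8 rose). Their test pointed up in 4+3N with a median of −0.04 (adjusted p = 0.000882; adjusted p = 0.69 with an estimated correlation) and up in 4N (adjusted p = 8.28e-11; adjusted p = 0.998 with an estimated correlation). Elongation factors rose in 4 of 11 cases in 4+3N and 3 in 4N (adjusted over the list alone 4 and 5). The test pointed up in 4+3N with a median of −0.03 (adjusted p = 4.75e-20; adjusted p = 0.0468 with an estimated correlation, and 0.213 with the block) and up in 4N (median 0.08, adjusted p = 2.31e-10; adjusted p = 0.13 with an estimated correlation). With no member passing, cell wall genes were lower in 4+3N (median −0.12, adjusted p = 2.39e-06) and 4N (median −0.04, adjusted p = 0.00792), and glycolysis (adjusted p = 0.00277) and aminoacyl-tRNA synthetase genes (adjusted p = 0.00388) were lower in 4+3N. With an estimated correlation each stood at an adjusted p = 0.69 in 4+3N and 0.998 in 4N. The block added amino-acid biosynthesis under Gcn4, lower in 4+3N (adjusted p = 0.0306; adjusted p = 0.603 with an estimated correlation).

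Of 5415 mRNA-seq genes, 12 passed in 4+3N (12 up; 197 at an unadjusted p under 0.05) and 10 in 4N (10 up; 201), with 9 shared. Between 4+3N and 4N, 0 passed by edgeR and 0 by DESeq2, with 132 at an unadjusted p under 0.05. In that comparison small-subunit (adjusted p = 0.000731), glycolysis (adjusted p = 0.000482) and large-subunit genes (adjusted p = 0.0093) were lower and elongation factors higher by the test with a median of −0.03 (adjusted p = 0.00192). None held with an estimated correlation (adjusted p = 0.951 for the first 3 and 0.689 for elongation factors). With the block, RPL1A at 0.59 (SE 0.09, adjusted p = 0.0128), TEF2 at 0.52 (SE 0.08, adjusted p = 0.0128) and TEF1 at 0.51 (SE 0.09, adjusted p = 0.0284) were higher in 4+3N than in 4N, 3 genes in all, and cell wall genes were lower (adjusted p = 0.026; adjusted p = 0.735 with an estimated correlation). The counts with the block were 13 in 4+3N and 16 in 4N. Without genes that have a near-identical copy, and without the block, 1 passed in 4+3N and 1 in 4N. The 4N count was 5 without Nonrandom replicate 1, 1 without 4N replicate 1 and 4 without 4N replicate 2. Without 4N replicate 1 RPL41A (adjusted p = 0.074), TEF2 (adjusted p = 0.104) and RPL35A (adjusted p = 0.203) no longer passed in 4N, nor did RPL35A without Nonrandom replicate 1 (adjusted p = 0.156) or 4N replicate 2 (adjusted p = 0.366). The 3 genes without a marked copy in 4N were YDR524W-C at 0.89 (SE 0.11, adjusted p = 0.00129), IRC15 at 0.73 (SE 0.14, adjusted p = 0.0399) and CSS1 at 0.69 (SE 0.13, adjusted p = 0.037). IRC15 (adjusted p from 0.105 to 0.649) and CSS1 (adjusted p from 0.0541 to 0.999) no longer passed without any one Nonrandom or 4N library, nor by DESeq2 (adjusted p = 0.17 and 0.127) or with copies left out (adjusted p = 0.12 each). CSS1 was lost without either 4+3N library (adjusted p = 0.0534 and 0.0536), IRC15 after thinning (adjusted p = 0.0698) and YDR524W-C without 4N replicate 1 (adjusted p = 0.0518).

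Whether fold changes of preparation in ribosome profiling recur in mRNA-seq was read across 5236 genes, which are not independent replicates. The Spearman correlation was 0.011 for 4N against Nonrandom, 0.083 for 4+3N against Nonrandom and 0.081 for 4+3N against 4N, and the Pearson correlations were 0.147, 0.293 and 0.082. Without the genes that have a near-identical copy the Spearman values were −0.004, 0.075 and 0.083 over 5051 genes. The Pearson values then fell to −0.008, 0.076 and 0.047. Within ribosome profiling, the changes of 4N and 4+3N against the shared Nonrandom libraries correlated at a Spearman of 0.647, where 20 simulations of unchanged groups with shared controls gave 0.451 (SD 0.013). The simulated libraries were independent, with no tie between equal replicate numbers. Their covariance was 0.1067 against 0.0118 in the simulations, and 1 gene, TAR1, rose in both, where independent lists would share 0.000377. With DualLigation the Spearman correlation was 0.138 for 4N (simulated 0.197) and 0.156 for 4+3N (simulated 0.186), with covariances of 0.058 and 0.0909 against 0.0119 and 0.0116. At 50 CPM or more these covariances were 0.0105 and 0.0259 against 0.0055 each, with Pearson correlations of 0.027 and 0.06 (simulated 0.199 and 0.195). With DualLigation, 0 genes of 4N and 1 gene of 4+3N rose in both, where independent lists would share 0.29 and 0.579. With one Nonrandom library for each comparison, so that no control was shared, the Spearman correlations were 0.195 and 0.15 for 4N and 4+3N, depending on which library went where (Pearson 0.686 and 0.684). With replicate 1 libraries for one comparison and replicate 2 libraries for the other they were 0.237 and 0.235 (Pearson 0.544 and 0.626). With DualLigation and one Nonrandom library each they were 0.102 and 0.024 for 4N and 0.124 and 0.076 for 4+3N. These splits were added after the data were seen.

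The footprint to mRNA ratio of each gene, a measure of translation efficiency relative to the other genes, was compared within each preparation (n = 2 libraries per assay). HAC1, the unfolded protein response activator whose unspliced mRNA is blocked by its intron, had log2 ratios of −5.06 in Nonrandom (SE 0.12, adjusted p = 2.29e-16), −5.40 in 4N and −5.10 in 4+3N. GCN4, controlled by upstream ORFs, stood at −4.87, −4.99 and −4.80, and CPA1, with an arginine-responsive upstream ORF, at −1.75, −1.59 and −1.70. SRO9, an RNA-binding protein of the La family, stood at 3.67, 3.59 and 3.65 (SE 0.13 in 4+3N), DED1, a translation initiation helicase, at 3.29, 3.31 and 3.49 (SE 0.11 in 4+3N), CHC1, clathrin heavy chain, at 2.90, 2.88 and 2.86 (SE 0.12 in 4+3N) and PAB1, the poly(A)-binding protein, at 2.41, 2.50 and 2.45 (SE 0.11 in 4+3N). YLR264C-A had 0 footprint reads in each preparation and was at least 446-fold, 630-fold and 515-fold lower in footprints than in mRNA on CPM. With the TMM factors of the ratio fit these bounds would be lower. The factors ran from 0.797 to 0.853 in footprint libraries and from 1.172 to 1.234 in mRNA-seq libraries. The log2 ratio of HIS3 stood at 0.83, 0.69 and 0.88.

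**Figure D3:**
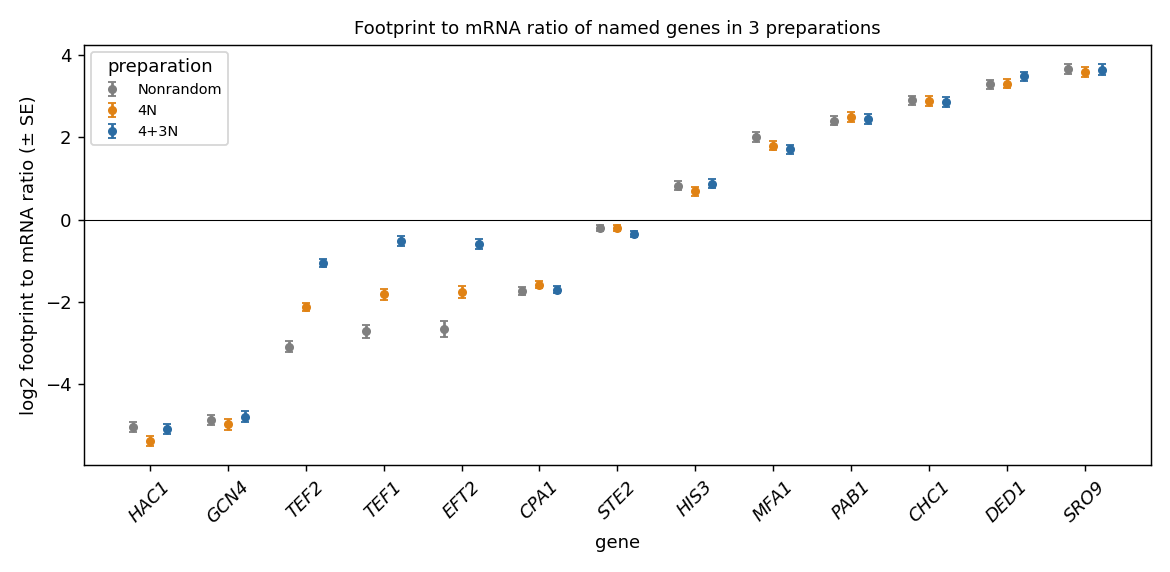
Points give the log2 footprint to mRNA ratio with its SE in the Nonrandom, 4N and 4+3N preparations (n = 2 libraries per assay) for 13 named genes. HAC1 lies between −5.40 and −5.06 in the 3 preparations, while TEF1 runs from −2.73 in Nonrandom to −0.53 in 4+3N.

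Counts of genes with higher and lower ratios are given by list in the order Nonrandom, 4N and 4+3N. Initiation factors and aminoacyl-tRNA synthetases held a call with an estimated correlation in some preparations, and the other lists of this paragraph in none (adjusted p of their lost calls from 0.0524 to 0.6). Initiation factors were higher in 20, 21 and 20 of 26 cases and lower in 1 each, with medians of 0.79, 0.86 and 0.91 (adjusted p = 5.44e-08, 1.49e-08 and 1.96e-09; adjusted p = 0.0183, 0.0526 and 0.00882 with an estimated correlation). Aminoacyl-tRNA synthetases were higher in 19, 20 and 20 of 20 and lower in 0 (adjusted p = 6.07e-08, 6.89e-09 and 5.48e-10; adjusted p = 0.0796, 0.077 and 0.043 with an estimated correlation), among them DPS1 at 1.68 (SE 0.09) in 4+3N. Ribosome biogenesis genes were higher in 42, 41 and 42 of 54 and lower in 2, 0 and 0, with RRP5, needed for both ribosomal subunits, at 1.99 (SE 0.09) in 4+3N. Respiratory chain and ATP synthase genes were higher in 31, 29 and 31 of 34 and lower in 1 each, with ATP1 at 2.04 (SE 0.10) in 4+3N. Large-subunit genes were higher in 50, 52 and 54 of 82 and lower in 18, 17 and 13, and small-subunit genes were higher in 32, 34 and 38 of 57 and lower in 10, 8 and 5. Mitochondrial ribosomal proteins were higher in 49, 49 and 48 of 70 and lower in 2, 2 and 3. Glycolysis genes were higher in 15, 16 and 16 of 21 and lower in 1, 2 and 1, with PFK2 at 2.15 (SE 0.09) in 4+3N, and tricarboxylic acid cycle genes were higher in 11, 14 and 14 of 15 and lower in 0. Chaperones were higher in 18, 19 and 19 of 24 and lower in 2, 1 and 1, although SSA3, a heat-inducible HSP70, stood at −5.24 (SE 0.22) in 4+3N. Proteasome genes were higher in 21, 24 and 25 of 34 and lower in 1 each, the vacuolar ATPase was higher in 12, 13 and 13 of 17 and lower in 1, 0 and 0, and cell wall genes were higher in 26, 26 and 24 of 29 and lower in 3 each, with SAG1, alpha-agglutinin, at −3.52 (SE 0.23) in 4+3N. Amino-acid biosynthesis genes under Gcn4 were higher in 23, 25 and 25 of 40 and lower in 9, 8 and 8.

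Among the remaining lists, genes with upstream ORFs or other translational control were higher in 6 of 24 in each preparation and lower in 12, 15 and 14 (adjusted p = 0.00734, 0.00686 and 0.00646; adjusted p = 0.233, 0.276 and 0.266 with an estimated correlation). Meiosis and sporulation genes were higher in 0 of 19 and lower in 14, 15 and 16 (adjusted p = 0.00608, 0.00248 and 0.00267; adjusted p = 0.233, 0.202 and 0.109 with an estimated correlation), with SMK1, a meiosis-specific kinase, at −4.78 (SE 0.38) in 4+3N. Elongation factors were higher in 5, 6 and 6 of 11 and lower in 5 each (median −0.14, 0.36 and 0.42; mean −0.64, −0.34 and 0.14), histones higher in 5, 5 and 6 of 10 and lower in 3, 3 and 2 (adjusted p = 0.0492 in 4+3N, 0.299 with an estimated correlation), and methionine and sulfate assimilation genes higher in 6, 8 and 7 of 19 and lower in 7, 7 and 6 (median 0.03 and mean −0.11 in 4N). General stress genes were higher in 14, 14 and 13 of 29 and lower in 10, 9 and 9, with positive medians (0.28, 0.14 and 0.22) and negative means (−0.23, −0.18 and −0.26). Genes of a cells were higher in 6, 7 and 6 of 13 and lower in 4, 5 and 4, and genes of alpha cells were higher in 1 of 4 and lower in 3, 2 and 2. Counts adjusted over the list alone differed from these by at most 2 members. Of the lists, 16, 16 and 17 passed by camera in Nonrandom, 4N and 4+3N, and with an estimated correlation 1, 0 and 2 did, the initiation factors and aminoacyl-tRNA synthetases named above. The others that passed had adjusted p-values with an estimated correlation from 0.0524, for mitochondrial ribosomal proteins in 4+3N, to 0.6, for the small subunit in 4N.

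Of 5523 genes, 4067 had a ratio that passed in Nonrandom (1930 higher, 2137 lower), 4111 in 4N (1951 higher, 2160 lower) and 4077 in 4+3N (1925 higher, 2152 lower), and 3602 passed in all 3 with the same direction. Across genes the ratios correlated at a Spearman of 0.975 for Nonrandom and 4N, 0.971 for Nonrandom and 4+3N and 0.977 for 4N and 4+3N. Footprint and mRNA libraries were not treated as paired. The ratios also carry any bias that acts on footprints and mRNA fragments differently, and they fell with coding length (Spearman −0.223, −0.222 and −0.224).

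The ratio itself differed between preparations for TEF1, TEF2 and EFT2. From Nonrandom to 4+3N the ratio of TEF1 rose by 2.19 (SE 0.20), that of EFT2 by 2.06 (SE 0.23) and that of TEF2 by 2.04 (SE 0.16), and from 4N to 4+3N by 1.29, 1.16 and 1.08. In levels, TEF1 went from −2.73 in Nonrandom to −1.82 in 4N and −0.53 in 4+3N. Elongation factors rose in 3 of 11 cases and fell in 0 from Nonrandom to 4+3N (adjusted over the list alone 5 rose; median 0.19, adjusted p = 1.89e-30; adjusted p = 0.00543 with an estimated correlation) and from 4N to 4+3N (adjusted over the list alone 4 rose; median 0.08, adjusted p = 7.76e-20; adjusted p = 0.0184 with an estimated correlation). From Nonrandom to 4N 0 passed (adjusted over the list alone 3 rose; median 0.12, adjusted p = 1.19e-05; adjusted p = 0.419 with an estimated correlation). From Nonrandom to 4+3N, with no member passing, 10 further lists were higher by camera, glycolysis (adjusted p = 1.86e-05), large-subunit and small-subunit genes (adjusted p = 4.17e-05 each) and aminoacyl-tRNA synthetases (adjusted p = 0.000254) with the smallest values, and genes of a cells were lower (adjusted p = 0.0206). None of these held with an estimated correlation (adjusted p from 0.281 to 0.514). From 4N to 4+3N large-subunit (adjusted p = 1.29e-12), small-subunit (adjusted p = 2.39e-07) and glycolysis genes (adjusted p = 2.54e-05) were higher, each with an adjusted p = 0.736 with an estimated correlation. From Nonrandom to 4N aminoacyl-tRNA synthetases, the proteasome and amino-acid biosynthesis under Gcn4 were higher (adjusted p = 0.0397 each), with an adjusted p = 0.691 each with an estimated correlation.

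By edgeR, 3 genes passed from Nonrandom to 4+3N (226 at an unadjusted p under 0.05), 3 from 4N to 4+3N (105) and 0 from Nonrandom to 4N (173; 2 by DESeq2). With a replicate block shared by the assays the counts were 5, 4 and 1, and with a block within each assay, added after seeing the data, 28 (22 up, 6 down), 7 and 4. Without genes that have a near-identical copy, and without a block, 0 passed in each. From Nonrandom to 4+3N the count was 5 without ribosome profiling 4N replicate 1 or replicate 2. From 4N to 4+3N it was 1 without mRNA-seq 4N replicate 1 or mRNA-seq 4+3N replicate 1, and from Nonrandom to 4N it was 1 without mRNA-seq Nonrandom replicate 2. EFT2 did not pass after thinning, at 1.53 (adjusted p = 0.162) from Nonrandom to 4+3N and 0.89 from 4N to 4+3N. From 4N to 4+3N TEF1 was lost without mRNA-seq 4N replicate 1 (adjusted p = 0.0857) or mRNA-seq 4+3N replicate 1 (adjusted p = 0.0516), and EFT2 without any one of ribosome profiling 4N replicate 2, ribosome profiling 4+3N replicate 1 and the 4 mRNA-seq libraries of 4N and 4+3N (adjusted p from 0.0647 to 0.201).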

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

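The tests of near-identical copies, of mRNA changes, of depth, of TAR1 and the 4 other ORFs, and of fold changes in DualLigation replicate 1 were chosen only after the results were seen. The other DualLigation tests were set before theirs were measured.

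Differences between groups called for a closer look in 3 places. The change from standard to low libraries differed between 4+3N and Nonrandom for 12 genes by an interaction test, the footprint to mRNA ratio differed between 4+3N and Nonrandom for 3 genes, and between 4+3N and 4N for 3 genes. The first pattern behind these counts is that TEF1, TEF2, EFT1, EFT2, RPL41A and RPL41B stood higher with random bases in the standard libraries. In Nonrandom low and 4+3N low, TEF1 stood at 1440 and 1590 CPM, TEF2 at 1320 and 1430 CPM, EFT2 at 515 and 455 CPM and EFT1 at 346 and 231 CPM, while RPL41A (217 and 576 CPM) and RPL41B (323 and 633 CPM) were still higher in 4+3N low. Depth is argued against as the whole cause, since their median log2 change was 1.65 (largest SE 0.80) in ribosome profiling 4N, whose totals lie within those of Nonrandom (the 3.29 of 4+3N after thinning decides nothing, as thinning keeps expected ratios), and a change in translation is argued against as the whole cause, since mRNA-seq, which does not pass through ribosomes, gave a median of 1.37. It stays open that reads of near-identical copies may have been kept more often in some libraries, because, with these 6 genes left out and each family counted once, 5 of the 10 genes over 2-fold higher with the block had a marked copy against 83 of 5155 others (odds ratio 61.1, one-sided Fisher's exact p = 3.02e-07). The ratios of TEF1, TEF2 and EFT2 did differ between preparations. All of these genes have a marked copy, so their ratios cannot show a change in translation. No label names a biological difference between the groups. Residuals of equal replicate numbers also correlated across the standard ribosome profiling groups other than DualLigation (0.574 to 0.776). Both argue against a difference in translation of these genes between Nonrandom, 4N and 4+3N.

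The second pattern is that TAR1, YLR154C-G, YLR162W, RRT15 and YPR159C-A held many reads in the low libraries. For YLR162W, RRT15 and YPR159C-A, 0 of them overlap an annotated ribosomal RNA gene, which argues against annotated overlap alone. Likeness in sequence could not be checked, so this lookup cannot decide whether fragments of ribosomal RNA were counted to them. It stays open whether fragments of ribosomal RNA were counted to TAR1 and YLR154C-G, which overlap its genes: they had 0 mRNA-seq reads, but YLR162W, RRT15 and YPR159C-A also had few (2, 5 and 0), so missing mRNA reads decide nothing. For the same reason they decide nothing on a change in translation of TAR1, although its 0 mRNA-seq reads would put its footprint to mRNA ratio in Nonrandom low at 10519 or more. TAR1 also went from 0 reads in Nonrandom to 110 ± 27.7 CPM (SD) in 4N and 129 ± 22.7 CPM in 4+3N. No label names a biological difference between these groups, so the values argue against a change in translation as the source there. For the low libraries, whose meaning is not stated, it was not tested further. How ribosomal RNA was removed from either assay is not described.

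The third pattern is the large set of fold changes in DualLigation. Replicates 2 and 3, in which YEF3 held the largest share, are argued against as the sole source, since 56.9% of the 2145 genes that passed by over 2-fold without replicate 1 were over 2-fold apart the same way in replicate 1 against 4+3N (0.1% the opposite way). A count of 3584 genes with replicate 1 as the only DualLigation library decides nothing, since the lone library was assumed to vary like the other groups. A state of the cells that moves proteasome genes together is argued against as the main source of their fold changes. The SD of these lay at percentile 65.7 of 10000 random lists matched on abundance and length. An SD does not change with a shift shared by all subunits, so such a shift beneath the wider spread stays open. Other differences between cultures were not tested. It stays open that few positions per gene may carry many of the counts, since the size of the fold change fell with coding length at matched abundance (partial Spearman rho −0.166 over 5298 genes).

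In data used only as another setting, the first of the 2 lists deposited for ribosome profiling Nonrandom replicate 1 held 3520161 reads, in no gene more than the second list.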

How the results depend on the processing

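The length offsets, the fit without DualLigation, the first list, the block within each assay and the correlations without copies or without shared controls were chosen only after the results were seen. Numbers of genes are given below as 4N against Nonrandom, 4+3N against Nonrandom and 4+3N against 4N, in that order where 3 are given, and where no reason is named the cause was not tested. Named single genes gave 597 entries, each a gene in a comparison where it passed, so a gene can be counted in several comparisons. Where an alternative gave a value, 0 reversed, 10585 stayed on the same side of the threshold and 180 were no longer past it. Only entries that had passed were followed, so reversals were unlikely from the outset. Of the counts and correlations, 240 values stayed within their limits, 99 moved and 1 reversed. The DualLigation and single-preparation ratio counts kept within 1.5 times under every setting other than leaving out libraries.

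With the replicate block (pairing by replicate number, in ribosome profiling without DualLigation, with a common coefficient of variation of 0.0268 where the unblocked fit with DualLigation had 0.2119), ribosome profiling gave 59, 490 and 32 genes, the low comparisons 198 (Nonrandom) and 135 (4+3N), their difference 51, mRNA-seq 16 for 4N and 3 for 4+3N against 4N, and the ratio differences 1 for 4N and 5 for 4+3N against Nonrandom. The block moved no other count by over 1.5 times. With block and length offsets these were 47, 439 and 29, then 160, 92 and 49, then 16 and 5. A block within each assay gave ratio differences of 4, 28 and 7. Fits without DualLigation gave 7, 16 and 6, and fits of the 2 compared groups 8, 14 and 6. For DualLigation, fits of the 2 compared groups gave 2092 against Nonrandom and 2026 against 4+3N. DESeq2 gave 2, 12 and 1 in ribosome profiling and ratio differences of 2 and 5 against Nonrandom. For 4+3N against Nonrandom in ribosome profiling, length offsets gave 1, thinning 4 and the first list 5. Without near-identical copies, which are then not tested, ribosome profiling gave 0 for 4N and 0 for 4+3N against Nonrandom, the low comparisons 20 and 10, their difference 2, mRNA-seq 1 for 4N and 1 for 4+3N against Nonrandom, and ratio differences 0 and 0 for 4+3N. Of the 103 list calls 12 held with an estimated correlation.

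Spearman correlations of ribosome profiling with mRNA-seq changes at 50 CPM or more were 0.052, 0.141 and 0.124, and without copies −0.004 (reversed), 0.075 and 0.083. Between preparations at 50 CPM or more they were 0.786 (4N and 4+3N), 0.091 (4N and DualLigation) and 0.131 (4+3N and DualLigation). With one Nonrandom library each, both ways round, they were 0.195 and 0.15, 0.102 and 0.024, and 0.124 and 0.076, and for 4N and 4+3N with equal replicate numbers only 0.237 and 0.235. Replicate variation after thinning was 30% in DualLigation, 5.8% in Nonrandom, 6.9% in 4N, 7.4% in 4+3N, 7.1% in Nonrandom low, 8% in 4+3N low, and in mRNA-seq 7.4% in Nonrandom and 4.9% in 4+3N. At 50 CPM or more it was 31.2% in DualLigation, 7.4% in 4+3N, 7% in Nonrandom low, 7.8% in 4+3N low, and in mRNA-seq 7.5% in Nonrandom and 6.4% in 4N.

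Leaving out each library in turn gave 0 to 3, 0 to 8 and 0 to 0 genes in ribosome profiling, 1880 to 3525 for DualLigation against Nonrandom and 1840 to 3490 against 4+3N, 36 to 89 for Nonrandom low, 20 to 48 for 4+3N low and 8 to 18 for their difference. In mRNA-seq it gave 1 to 8, 11 to 14 and 0 to 0, for ratios 3619 to 4082 (Nonrandom), 3531 to 4145 (4N) and 3586 to 4107 (4+3N), and for ratio differences 0 to 1, 3 to 5 and 1 to 4. A group left with 1 library was assumed to vary like the others. The planned corrections for GC and coding length, and for the replicate block with GC and coding length, were not run, since no sequences were at hand. Depth was lowest in 4+3N low replicate 1, where 3 counts stand for 3.63 CPM.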

Other observations

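The overlap with small nucleolar RNA genes below was looked up only after the results were seen. IMD4 stood at 38500 CPM in DualLigation and 445 CPM in Nonrandom, while its near-identical copy IMD3 stood at 271 CPM and 459 CPM. The reference annotation places SNR54 within IMD4 and SNR44 within RPS22B. Of 9 tested genes that overlap an annotated small nucleolar RNA gene, 6 rose in DualLigation against Nonrandom, 2 fell and 1 did not pass. The other rises were of EFB1 at 2.19, RPL7B at 1.62, NOG2 at 0.57 and ASC1 at 0.55, RPL7A fell by 1.43, YJL047C-A fell by 3.09 and TEF4 did not pass. Of all 5300 genes 1535 rose.

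Some transcripts had mRNA reads and few or no footprint reads. The meiotic gene RED1, part of the meiotic chromosome axis, had 0 footprint reads in Nonrandom (at least 79-fold lower in footprints than in mRNA). NDJ1, a meiotic telomere protein, had 0 footprint reads in 4N (at least 131-fold lower). Both bounds are on CPM and would be lower with the TMM factors of the ratio fit. In the other 2 preparations RED1 had 3 reads each and NDJ1 1 each. MFA1, by contrast, had a log2 ratio of 1.72 (SE 0.11) in 4+3N.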
